A study of Homo sapiens with 9 samples.

How the data were processed

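RNA of T98G cells was measured on 9 Affymetrix expression arrays of 1 design, 3 from cells deprived of serum for 3 days, 3 from cells held in contact inhibition for 3 days and 3 from asynchronously growing cells. T98G is an established human glioblastoma line. The groups and the replicate numbers were taken from the sample titles. The labels do not say whether the 3 replicates of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

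The values were probe set intensities on a linear scale, as the authors deposited them in 1 table of 22277 probe sets. The software that summarised the probes and the scaling between arrays were not given in the sources used here. Detection calls were not used here. The intensities themselves showed 2 scales. Replicate 3 of each group had a mean, trimmed by 2% at each end, of 150.0, and the other 6 arrays had trimmed means from 172.7 to 276.9. These 3 and 6 arrays were treated as 2 technical batches, each of which held all 3 groups. Array medians ran from 43.7 to 87.6 intensity units. No 2 arrays of a group were copies of each other: at least 96.4% of the probe sets differed by over 1% between any such pair. For arrays no read depth applies, and the number of arrays limits the precision.

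Probe sets were named through the platform annotation given with the table, with symbols checked through Entrez identifiers against a RefSeq gene table. A single gene was named for 19064 probe sets, of which 19052 identifiers matched and 0 symbols changed. A further 1043 probe sets named several genes, 2108 were unnamed here and 62 were array controls, and all of these were left out of the gene tests. Of the 11963 genes, 4310 had more than 1 probe set, and the probe set with the highest mean over all 9 arrays stood for the gene. No genome build is named in the sources used here, so no positions are given.

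The test, the filter, the gene lists, the rule for naming genes and all alternatives but 3 were chosen before the data were examined. Intensities were converted to log2(value + 16). By a rule fixed in advance the arrays did not count as already normalized, so quantile normalization was applied. Changes are therefore differences on the log2(value + 16) scale, which understates the change of dim genes. Genes were tested if their mean exceeded the 40th percentile of the single-gene probe sets, 5.80 on the log2 scale or an intensity of 39.6, which left 7607 genes. Probe sets with the suffix _x_at or _s_at, which can match several transcripts or genes, stood for 3644 of them. Analysis used R 4.3.3 and limma 3.58.1. One linear model with a mean per group was fitted to all 9 arrays with lmFit, followed by eBayes with an intensity trend. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and a gene was called at an adjusted p under 0.05. Errors of changes are standard errors of this model.

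The 39 gene lists held 1040 genes, of which 932 had a probe set and 813 were tested. Lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. The same test with an estimated correlation and limma's fry were run beside it. Camera compares the genes of a list with all other tested genes, whereas fry asks whether the genes of a list move one way on balance and compares them with nothing else. The named genes were fixed by rule. For each contrast these were the 6 largest rises and the 6 largest falls among called genes whose 3 arrays in one group all lay above the 3 of the other, 2 members of each called list with the largest called change in its direction, and 10 cell cycle regulators, of which 9 had a single-gene probe set. For changes shared by both arrests, the 5 rises and 5 falls with the largest smaller change were added. This gave 116 genes, and a gene named outside the rule is said to be so.

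The linear model and its calls, without the normalization and the choice of probe sets, were tried on simulated data for all 7607 genes. Each gene had independent noise, and only 67 genes were changed by 0.5, 67 by 1 and 66 by 2. Far more genes were called in the real data, so the rates below need not hold there. Of genes changed by 1 on the log2 scale, 97.0% were recovered for serum-deprived against asynchronous cells, 97.0% for contact-inhibited against asynchronous cells and 95.5% for serum-deprived against contact-inhibited cells. At a change of 0.5 the shares were 52.2%, 62.7% and 50.7%. False calls made up 4.60%, 5.98% and 4.09% of the calls. Both arrests were compared with the same asynchronous arrays, so overlap and correlation are given beside 100 simulations of unchanged groups that shared those arrays. With 3 such arrays no split into parts of at least 2 each was possible.

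The alternatives changed the pseudocount, the normalization, the filter, the moderation, the groups in the fit, the array weights, the treatment of several probe sets per gene, the fold threshold and the replicate number as a block, and left out each array in turn. Scaling to a common trimmed mean, the scaling batch as a block and the 6 arrays alone were added after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.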

Results

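Gene expression was profiled in T98G human glioblastoma cells in 3 states, with 3 arrays each: arrest by serum deprivation for 3 days, arrest by contact inhibition for 3 days, and asynchronous growth. The design asks which transcripts change when these cells stop dividing, which changes are common to both ways of arrest, and which differ between them. Whether the replicates of a group were independent cultures is not given, so the p-values measure the spread between these samples. Arrays of one group correlated at 0.978 to 0.985 over 9 pairs, and arrays of different groups at 0.940 to 0.963 over 27 pairs. The first principal component held 53% of the variance and separated asynchronous from arrested cells, with serum-deprived arrays farther out than contact-inhibited ones. The next component, with 28.2%, set contact-inhibited arrays (−26.18 to −22.88) apart from serum-deprived (14.17 to 15.95) and asynchronous ones (7.66 to 10.85). The difference between 3' and 5' probe sets of GAPDH, a sign of RNA quality, was −0.205 ± 0.024 (SD, n = 3) in serum-deprived, −0.145 ± 0.080 in contact-inhibited and −0.114 ± 0.051 in asynchronous cells. For serum-deprived against asynchronous cells the two-sided exact permutation p was 0.1, the smallest that 3 against 3 arrays allow, and for ACTB no such p was below 0.3.

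Genes of cell division were lower in serum-deprived than in asynchronous cells. CDC20, which activates the anaphase-promoting complex, fell 15-fold (log2 change −3.91 ± 0.11 SE, adjusted p = 1.31e-10, n = 3 arrays per group). On the log2 scale TYMS, the thymidylate synthase, changed by −3.61, the topoisomerase TOP2A by −3.58, the cytidine deaminase APOBEC3B by −3.56, the spindle gene ASPM by −3.53 and HJURP, the chaperone of the centromeric histone, by −3.52. GPNMB, a transmembrane glycoprotein of lysosomes and melanosomes, had the largest rise, 14.9-fold (log2 change 3.89 ± 0.10 SE, adjusted p = 6.93e-11), and the matrix Gla protein MGP rose 12.3-fold. HPGD, which inactivates prostaglandins, and SCG2, a secretory granule protein, both rose by 3.31 on the log2 scale, and the matrix genes TNC and DPT by 2.94 and 2.82. As the mean of its probe sets TYMS changed by −2.15.

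Of 51 tested genes of G2/M and mitosis, 51 fell in serum-deprived cells, with a median change of −2.78, and of 44 genes of G1/S and DNA replication, 43 fell, with a median of −2.10. The replication gene CDC45 fell by 3.50. DNA repair and recombination genes fell in 15 of 16 cases, median −1.43, among them RAD51AP1 at −3.40 and RAD54L at −3.05. Of 20 nucleotide synthesis genes 19 fell (median −0.84, CTPS1 −1.83, MTHFD1 −1.74), as did 22 of 25 ribosome biogenesis and MYC target genes (median −0.79, DDX21 −1.15, RRP9 −1.01). Splicing genes fell in 23 of 29 cases (median −0.71, SNRPD1 −1.51, HNRNPA2B1 −1.39) and chaperones in 15 of 18 (median −0.73, CCT5 −1.28, FKBP4 −1.11). Mitochondrial ribosome genes (24 lower of 42, median −0.43, HSPE1 −1.35, MRPL19 −1.24) and oxidative phosphorylation genes (19 lower of 47, median −0.21, CYC1 −0.75, COX5A −0.61) fell by smaller amounts. With a pseudocount of 64 CDC45 changed by −2.21 and RAD54L by −1.98, without x and s probe sets SNRPD1 changed by −0.68, and with no normalization COX5A changed by −0.96.

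Extracellular matrix genes rose in 22 of 30 cases in serum-deprived cells, with a median of 0.89, led by TNC and the collagen COL3A1, which rose by 2.63. Lysosome and autophagy genes rose in 30 of 41 cases (median 0.59), with the sphingolipid activator precursor PSAP and the cathepsin CTSF both 2.00 higher. Immediate early genes rose in 13 of 21 cases and fell in 0 (median 0.47), led by the MAP kinase phosphatase DUSP1 at 2.38 and JUN at 1.88. With an estimated correlation the calls of 12 of the 20 called lists held, all of those given so far for serum deprivation. As the mean of their probe sets COL3A1 was at 1.70 and DUSP1 at 1.11, JUN was at 1.09 without x and s probe sets, and the other probe set of PSAP gave 1.19. With no normalization the call of the oxidative phosphorylation list was lost (adjusted p = 0.0964).

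The other called lists of this comparison lost their call with an estimated correlation. Interferon response genes were higher in 23 of 32 cases and lower in 3 (median 0.55, OAS1 1.27, IFI6 1.03), with adjusted p = 7.11e-05 and adjusted p = 0.0581 with an estimated correlation. Mesenchymal markers were higher in 8 of 12 cases (median 0.48, FN1 1.74, S100A4 1.61), adjusted p = 0.01 and adjusted p = 0.0581 with an estimated correlation. FOXO targets were higher in 8 of 13 cases (median 0.49, PINK1 0.97, CITED2 0.92), adjusted p = 0.021 and adjusted p = 0.0745 with an estimated correlation. Matrix proteases and inhibitors were higher in 10 of 23 cases (median 0.24, TIMP1 1.61, ADAMTS1 1.28), adjusted p = 0.0231 and adjusted p = 0.073 with an estimated correlation. Growth factor receptors and ligands were higher in 8 of 19 cases (median 0.35, FGFR1 1.31 but 0.10 without x and s probe sets), adjusted p = 0.0489 and adjusted p = 0.255 with an estimated correlation. Proteasome genes were lower in 13 of 26 cases (median −0.21, PSMA3 −0.75, PSMD12 −0.72), adjusted p = 0.00065 and adjusted p = 0.0581 with an estimated correlation. TCA cycle genes were lower in 10 of 17 cases (median −0.34, CS −0.85, IDH2 −0.82 but −0.09 without x and s probe sets), adjusted p = 0.0335 and adjusted p = 0.274 with an estimated correlation. RB and E2F family genes were lower in 7 of 11 cases (median −0.52, MYBL2 −2.60), adjusted p = 0.0167 and adjusted p = 0.0875 with an estimated correlation. The growth factor list also lost its call without serum-deprived replicate 1 (adjusted p = 0.211), 2 (0.121) or 3 (0.0535) or asynchronous replicate 2 (0.0641) or 3 (0.0506), and the TCA list without serum-deprived replicate 1 (0.0618) or asynchronous replicate 3 (0.0506). With no normalization the calls of the TCA (adjusted p = 0.127), matrix protease (0.0741), proteasome (0.0727) and growth factor (0.0766) lists were lost, and with trimmed-mean scaling that of the growth factor list (0.0618). With no normalization the calls of PINK1 (0.59, adjusted p = 0.221), CITED2 (0.50, 0.318) and IFI6 (0.78, 0.0708) were also lost, and PSMA3 and PSMD12 were at −1.14 and −1.12. The other probe set above the filter gave 0.61 for OAS1 and −0.13 for PSMD12. NRG1, a growth factor of that list, was 1.24 higher by its brightest probe set, but another of its probe sets gave −0.38 and the others above the filter 0.89 and 0.92.

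In all, 3585 of 7607 genes, or 47.1%, were called between serum-deprived and asynchronous cells in limma's test, 1810 higher and 1775 lower, and 721 of them differed at least 2-fold (313 higher, 408 lower). The arrays of both groups did not overlap for 56.5% of genes, against 10% by chance. With median centring in place of quantile normalization the calls split into 1168 higher and 2238 lower genes, and with no normalization into 209 and 1104; the median of all genes was then −0.099 and −0.262, against 0.026. With the scaling batch as a block 3773 genes were called, and 2977 in the 6 arrays of the larger batch alone; the other batch had 1 array per group and no test.

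**Figure D1:**
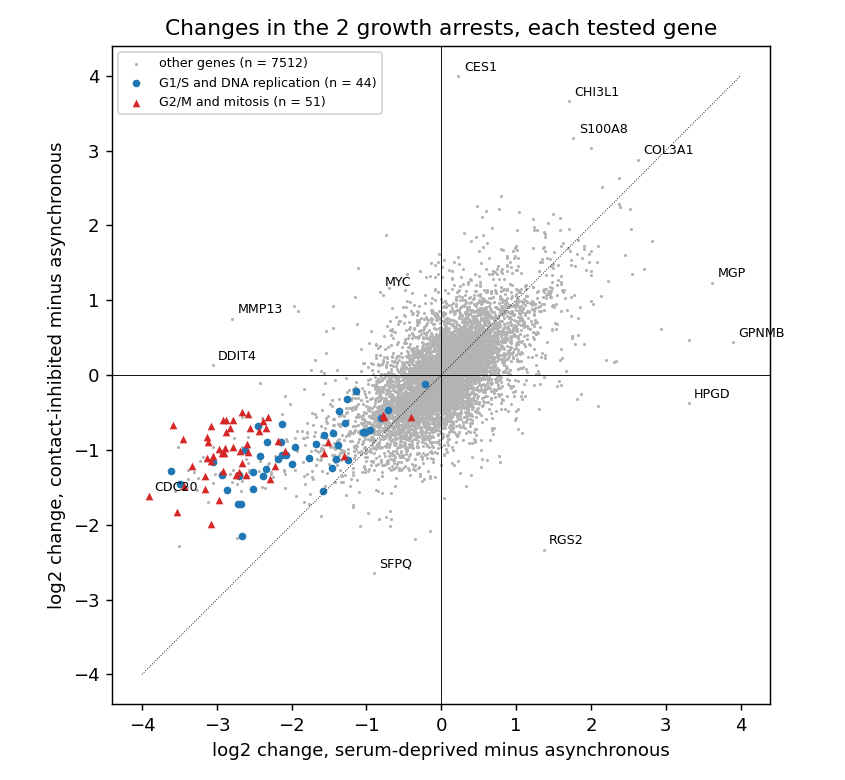
Log2 change of each of 7607 tested genes in serum-deprived (horizontal) and contact-inhibited (vertical) against asynchronous cells, each point the difference of means of 3 arrays, with the genes of G1/S and DNA replication (44, circles) and of G2/M and mitosis (51, triangles) marked and the dotted line marking equal changes. The correlation across genes was 0.659, and the G2/M genes had a median change of −2.78 in serum-deprived and −0.98 in contact-inhibited cells.

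Cell cycle genes were also lower in contact-inhibited cells, but most of the largest changes were in other genes. The carboxylesterase CES1 rose 16-fold (log2 change 4.0 ± 0.10 SE, adjusted p = 1.84e-10, n = 3 arrays per group), the secreted chitinase-like protein CHI3L1 rose 12.6-fold and the calcium-binding S100A8 rose 8.96-fold. SAT1, which acetylates polyamines, rose by 3.04 on the log2 scale, COL3A1 by 2.88 and DUSP1 by 2.63. The splicing factor SFPQ had the largest fall, −2.65 ± 0.08 SE, followed by RGS2, a regulator of G protein signalling, at −2.33, the kinetochore gene ZWINT at −2.29, ARMH3 at −2.19, the defensin DEFB1 at −2.17 and the origin licensing gene CDC6 at −2.15. The probe sets of SFPQ gave −2.65, −2.21, 0.52 and 0.12, and the other probe set of ARMH3 gave −0.48. ARMH3 was at −1.23 with a pseudocount of 64, and as the mean of their probe sets ARMH3 was at −1.33, SFPQ at −1.06, CHI3L1 at 2.34 and DUSP1 at 1.72.

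In contact-inhibited cells all 51 tested G2/M genes fell, with a median of −0.98, and 41 of 44 G1/S genes fell, with a median of −1.08. CENPF fell by 2.00, ASPM by 1.83 and CCNE2 by 1.73. DNA repair genes fell in 14 of 16 cases (median −0.88, RAD51AP1 −1.49, TIPIN −1.43) and nucleotide synthesis genes in 12 of 20 (median −0.45, CTPS1 −1.35, ADSL −1.30). Proteasome genes fell in 24 of 26 cases, with a median of −0.56, among them PSMC6 at −1.22 and PSMD14 at −0.96. Chaperones fell in 15 of 18 cases (median −0.67, CCT2 −1.20, HSPH1 −1.17), ribosome biogenesis and MYC target genes in 18 of 25 (median −0.48) and splicing genes in 21 of 29 (median −0.50, SRSF3 −1.58, SNRPF −1.34). ODC1, which starts polyamine synthesis and is counted with the MYC targets, fell by 2.02, and RRP9 by 1.25. Mitochondrial ribosome genes fell in 28 of 42 cases (median −0.51, MRPL15 −1.19, HSPE1 −1.13) and oxidative phosphorylation genes in 21 of 47 (median −0.19, NDUFS6 −0.84, NDUFB3 −0.62), NDUFB3 not being called with no normalization (−0.73, adjusted p = 0.138). CENPF was at −1.31 as the mean of its probe sets.

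Extracellular matrix genes rose in 25 of 30 cases in contact-inhibited cells (median 0.69, POSTN 1.73), and matrix proteases and inhibitors in 16 of 23 (median 0.57, TIMP1 1.22, CTSB 1.15). Growth arrest genes and CDK inhibitors rose in 9 of 15 cases and fell in 0 (median 0.57), led by GADD45A, a DNA damage-inducible gene, at 2.16 and the thioredoxin inhibitor TXNIP at 1.68. NF-kB targets and inflammatory cytokines rose in 11 of 17 cases (median 0.61), with CXCL8 1.53 and LIF 1.35 higher. Lysosome genes rose in 26 of 41 cases (median 0.48, TPP1 1.46, WIPI1 1.40), FOXO targets in 8 of 13 (median 0.52, IRS2 1.67, TRIB1 1.35), immediate early genes in 11 of 21 (median 0.39, DUSP5 2.09) and mesenchymal markers in 7 of 12 (median 0.48, FN1 1.48, ACTA2 0.87). These and the lists that fell make up 18 of the 21 called lists, and their calls held with an estimated correlation. ACTA2 was not called as the mean of its probe sets (0.44, adjusted p = 0.0514) or with no normalization (0.76, adjusted p = 0.0999). With a pseudocount of 64 POSTN was at 1.11 and CXCL8 at 0.88, TPP1 was at 0.93 as the mean of its probe sets, and the other probe set of IRS2 gave 1.04. The oxidative phosphorylation list lost its call with no normalization (adjusted p = 0.0898).

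Genes of the unfolded protein and amino acid response were higher in 16 of 28 cases (median 0.37, HERPUD1 1.67, DNAJB9 1.18), adjusted p = 0.0135 and adjusted p = 0.0989 with an estimated correlation. The insulin and IGF axis was higher in 7 of 12 cases (median 0.35, IGF1R 0.90), adjusted p = 0.0148 and adjusted p = 0.0619 with an estimated correlation. Growth factor receptors and ligands were higher in 9 of 19 cases (median 0.27, NRG1 0.95, KITLG 0.76), adjusted p = 0.0247 and adjusted p = 0.217 with an estimated correlation. With no normalization the adjusted p of these 3 lists was 0.0516, 0.0559 and 0.0774, and IGF1R (0.79, adjusted p = 0.0812), NRG1 (0.85, 0.0597) and KITLG (0.73, 0.121) were not called. The other probe set of IGF1R above the filter gave 0.18, and KITLG was at 0.44 as the mean of its probe sets. NRG1 was at 1.73, 1.73 and 1.74 without serum-deprived replicate 1, 2 or 3, when another of its probe sets was the brightest. Among markers of other cell types, 2 of 5 tested immune genes were higher in contact-inhibited cells, the class II antigen presentation genes CD74 at 1.90 and HLA-DRA at 1.51 (list adjusted p = 0.0672), both named after their values were seen. Neuronal (adjusted p = 0.321) and astrocyte and glial markers (adjusted p = 0.551) were not called, and the 4 tested epithelial markers were too few for a list test. Of these, chosen after their values were seen, KRT18 changed by −1.81, and MUC1 (0.07), KRT8 (0.49) and ELF3 (0.24) were not called.

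Of 7607 genes, 3708 or 48.7% were called between contact-inhibited and asynchronous cells, 1725 higher and 1983 lower, and 611 differed at least 2-fold (287 higher, 324 lower). The arrays of both groups did not overlap for 56.2% of genes, against 10% by chance. With median centring the split was 1313 higher and 2288 lower, and with no normalization 311 and 629. With the scaling batch as a block 3919 genes were called, and 2949 in the 6 arrays of the larger batch. In those 6 arrays 21 lists were called, and 20 for serum-deprived against asynchronous cells.

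Both arrests shared a large part of their changes. Called in both and in one direction were 2264 genes, 1066 higher and 1198 lower. Independent lists would give 410 and 463, and the simulated unchanged groups gave a mean and a maximum of 0 such genes. With no gene changed, hardly any can be called in either contrast. That 0 therefore does not measure the overlap that shared arrays create among changed genes. The rises with the largest smaller change were those of COL3A1, DUSP1, CLCA2 (2.38 in serum-deprived and 2.29 in contact-inhibited cells), LOC100996756 (2.39 and 2.25) and DEPP1 (2.52 and 2.22). Among falls these were ZWINT (−3.50 and −2.29), DEFB1 (−2.74 and −2.17), CDC6 (−2.66 and −2.15), CENPF (−3.08 and −2.00) and ASPM (−3.53 and −1.83). With a pseudocount of 64 LOC100996756 was at 1.16 and 1.06, DEPP1 at 1.45 in contact-inhibited and DEFB1 at −1.74 in serum-deprived cells, and as the mean of their probe sets CENPF was at −1.79 and −1.31, COL3A1 at 1.70 and DUSP1 at 1.11 in serum-deprived cells. Across genes, which are not independent replicates, the changes of the 2 arrests correlated at 0.659 (jackknife SE over arrays 0.026, Spearman 0.650), against 0.499 in the simulations, whose highest value was 0.535. The covariance was 0.252 against 0.0115 simulated, a difference of 0.241. Part of the excess overlap may come from the shared asynchronous arrays. The correlation was 0.640, 0.646 and 0.636 among the arrays of replicate numbers 1, 2 and 3, and 0.659 in the 6 arrays of the larger batch, where 1775 genes were shared, against 2399 with the scaling batch as a block. Median centring gave 694 shared higher and 1513 shared lower genes, and no normalization 114 and 432.

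**Figure D2:**
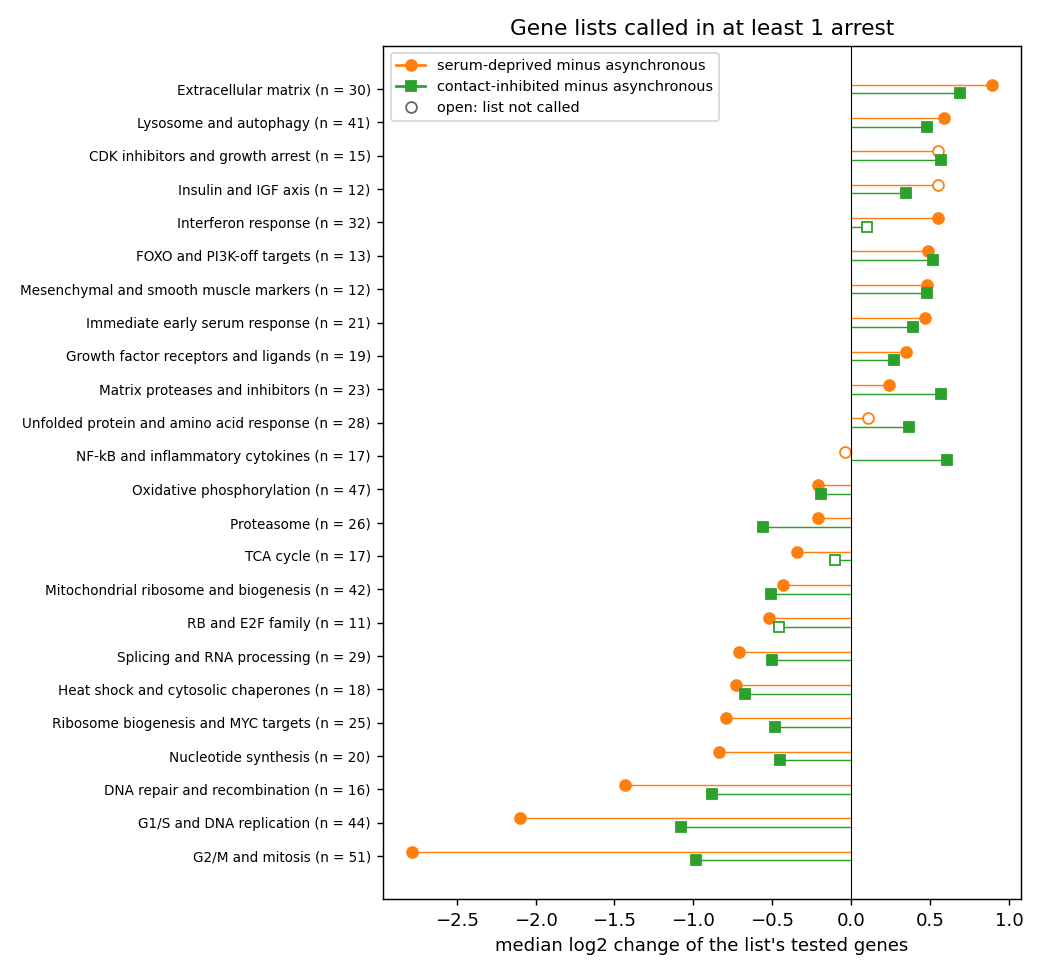
Median log2 change against asynchronous cells of the tested genes of each list called in at least 1 arrest, for serum-deprived (circles) and contact-inhibited cells (squares), with open symbols where the list was not called and n the number of tested genes. The G2/M list lay at −2.78 and −0.98 and the extracellular matrix list at 0.89 and 0.69.

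The direct contrast between serum-deprived and contact-inhibited cells tests where the 2 arrests differed. RGS2 was 13-fold higher in serum-deprived cells (log2 difference 3.70 ± 0.09 SE, adjusted p = 2.73e-10, n = 3 arrays per group), and HPGD 12.9-fold, GPNMB 11-fold, SCG2 7.16-fold, the glycogen-targeting phosphatase subunit PPP1R3C 5.70-fold and MGP 5.23-fold higher. Higher in contact-inhibited cells were CES1 (log2 difference −3.77), the collagenases MMP13 (−3.55) and MMP1 (−2.76), the stress-induced mTOR inhibitor DDIT4 (−3.19), TOP2A (−2.92) and the retinoid-responsive RARRES1 (−2.89).

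Cell cycle transcripts were lower in serum-deprived than in contact-inhibited cells: 47 of 51 G2/M genes (median −1.77, PRC1 −2.60), 35 of 44 G1/S genes (median −0.97, TYMS −2.33, CDC45 −2.03) and 13 of 16 DNA repair genes (median −0.74, EXO1 −2.10, RAD54L −2.09). These 3 lists kept their call with an estimated correlation. TYMS was at −1.41 as the mean of its probe sets, RAD54L at −1.22 with a pseudocount of 64, and CDC45 at −3.12 and −1.07 with pseudocounts of 1 and 64. By replicate number, the G2/M median was −2.74, −2.71 and −2.75 in serum-deprived and −0.91, −0.96 and −0.97 in contact-inhibited cells, each against the asynchronous array of that number.

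The remaining 6 called lists lost their call with an estimated correlation. Proteasome genes were higher in serum-deprived cells in 18 of 26 cases (median 0.29, PSMC2 0.69, PSMC6 0.62), adjusted p = 0.000131 and adjusted p = 0.0982 with an estimated correlation. Unfolded protein and amino acid response genes were lower in 13 of 28 cases (median −0.24), adjusted p = 0.00232 and adjusted p = 0.128 with an estimated correlation. In that list CHAC1, a glutathione-degrading enzyme, differed by −2.13 and the asparagine synthetase ASNS by −2.07. Nucleotide synthesis genes were lower in 11 of 20 cases (median −0.43, MTHFD2 −1.59, PRPS2 −0.82), adjusted p = 0.0065 and adjusted p = 0.14 with an estimated correlation. CDK inhibitor and growth arrest genes were lower in 8 of 15 cases (median −0.26, DDIT4 −3.19, GADD45B −1.52), adjusted p = 0.0183 and adjusted p = 0.128 with an estimated correlation. TGF-beta targets were lower in 9 of 16 cases (median −0.39, ID1 −1.81, LOX −1.45), adjusted p = 0.0441 and adjusted p = 0.15 with an estimated correlation. Fatty acid synthesis genes were lower in 5 of 9 cases (median −0.24, ACACA −0.81, FASN −0.77), adjusted p = 0.0448 and adjusted p = 0.159 with an estimated correlation. The fatty acid list lost its call without serum-deprived replicate 1 (adjusted p = 0.0597) or 3 (0.058) or asynchronous replicate 1 (0.0569), with no normalization (0.186), median centring (0.068) or the mean of probe sets (0.0817) and in the 6 arrays of the larger batch (0.0595), and the TGF-beta list without serum-deprived replicate 1 (0.0522) or asynchronous replicate 1 (0.0677). The proteasome list had a median of 0.01 and lost its call with no normalization (adjusted p = 0.186), as did PSMC2 (0.40, adjusted p = 0.617) and PSMC6 (0.42, 0.574). CHAC1 was at −1.33 with a pseudocount of 64 and GADD45B at −0.81 as the mean of its probe sets.

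Interferon response genes, called in serum-deprived cells (adjusted p = 0.0581 with an estimated correlation) but not in contact-inhibited cells (median 0.10, adjusted p = 0.0788), were not called in the direct contrast (median 0.19, adjusted p = 0.172), nor were NF-kB targets (median −0.53, adjusted p = 0.0843), called in contact-inhibited but not in serum-deprived cells. The contact-inhibited interferon call was made without contact-inhibited replicate 2 (adjusted p = 0.041) or asynchronous replicate 1 (0.0436), and the direct NF-kB call without contact-inhibited replicate 2 (0.0456). With no normalization both lists were called in the direct contrast, interferon response genes at a median of 0.03 (adjusted p = 0.0287) and NF-kB targets at −0.67 (adjusted p = 0.0147).

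Between the 2 arrests 2858 genes, or 37.6%, were called in limma's test, 1515 higher and 1343 lower in serum-deprived cells, and 431 differed at least 2-fold (154 higher, 277 lower). The arrays of both arrests did not overlap for 47.7% of genes, against 10% by chance. With no normalization the split was 102 higher and 495 lower. With the scaling batch as a block 3084 genes were called, and 2069 genes and 8 lists in the 6 arrays of the larger batch. Of the genes called in both arrests against asynchronous cells, 891 also differed between the arrests.

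Among the regulators fixed in advance, MYC moved in opposite directions, with −0.82 ± 0.15 (SE, adjusted p = 0.000664) in serum-deprived and 1.12 ± 0.15 (adjusted p = 7.09e-05) in contact-inhibited cells, a difference of −1.94 (adjusted p = 1.29e-06). CDKN1A, which encodes the CDK inhibitor p21, moved likewise, by −0.62 (adjusted p = 0.00772) and 0.57 (adjusted p = 0.0127), a difference of −1.20 (adjusted p = 0.00013); in the 6 arrays of the larger batch its changes were −0.52 (adjusted p = 0.0971) and 0.57 (adjusted p = 0.0692). E2F1 changed by −1.80 and −0.64, with its other probe set at −2.32 and −1.81, and the difference between the arrests, −1.16, was −0.51 (adjusted p = 0.221) without x and s probe sets and −0.74 with a pseudocount of 64. RBL1, the pocket protein p107, changed by −1.59 and −1.28 (−0.92 and −0.76 with a pseudocount of 64), and MKI67 by −2.30 and −1.39. CDKN1B, the CDK inhibitor p27, rose by 0.55 in serum-deprived cells (adjusted p = 0.00912; 0.30 and adjusted p = 0.218 with median centring) and stood at 0.34 in contact-inhibited cells (adjusted p = 0.0784), where it was called without contact-inhibited replicate 3 (0.0136) or asynchronous replicate 1 (0.0464), with array weights (0.0346), with the scaling batch as a block (0.0153) and in the 6 arrays of the larger batch (0.0415). The difference of CDKN1B between the arrests was not called in the main setting. CCND1 fell by 0.65 in serum-deprived cells and by 0.43 in contact-inhibited cells (adjusted p = 0.034), the latter not called without contact-inhibited replicate 2 (0.0907) or 3 (0.111) or asynchronous replicate 1 (0.105), 2 (0.0575) or 3 (0.0568), nor with no filter (0.0643) or in those 6 arrays (0.144). RBL2, the pocket protein p130, was at 0.14 in serum-deprived (adjusted p = 0.592) and 0.68 in contact-inhibited cells (adjusted p = 0.0132), the latter not called without contact-inhibited replicate 1 (0.0561) or asynchronous replicate 3 (0.0543). The difference of RBL2 between the arrests was called in the main setting but lost its call under several alternatives. Among these were a pseudocount of 1 (−0.56, adjusted p = 0.0519), no filter (−0.54, 0.0927) and leaving out contact-inhibited replicate 1 (−0.36, 0.189). E2F4 was at 0.20 (adjusted p = 0.137) and 0.10 (adjusted p = 0.438), with its other probe set at −0.39 and −0.81, and in serum-deprived cells it was called at 0.31 without serum-deprived replicate 1 (0.0138) and at 0.26 with array weights (0.0249). In contact-inhibited cells it was called in the other direction, at −0.35 (adjusted p = 0.015), as the mean of its probe sets. With no normalization the calls of CDKN1B in serum-deprived (adjusted p = 0.841) and of CDKN1A (0.423), E2F1 (0.101), CCND1 (0.25) and RBL2 (0.296) in contact-inhibited cells were lost.

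**Figure D3:**
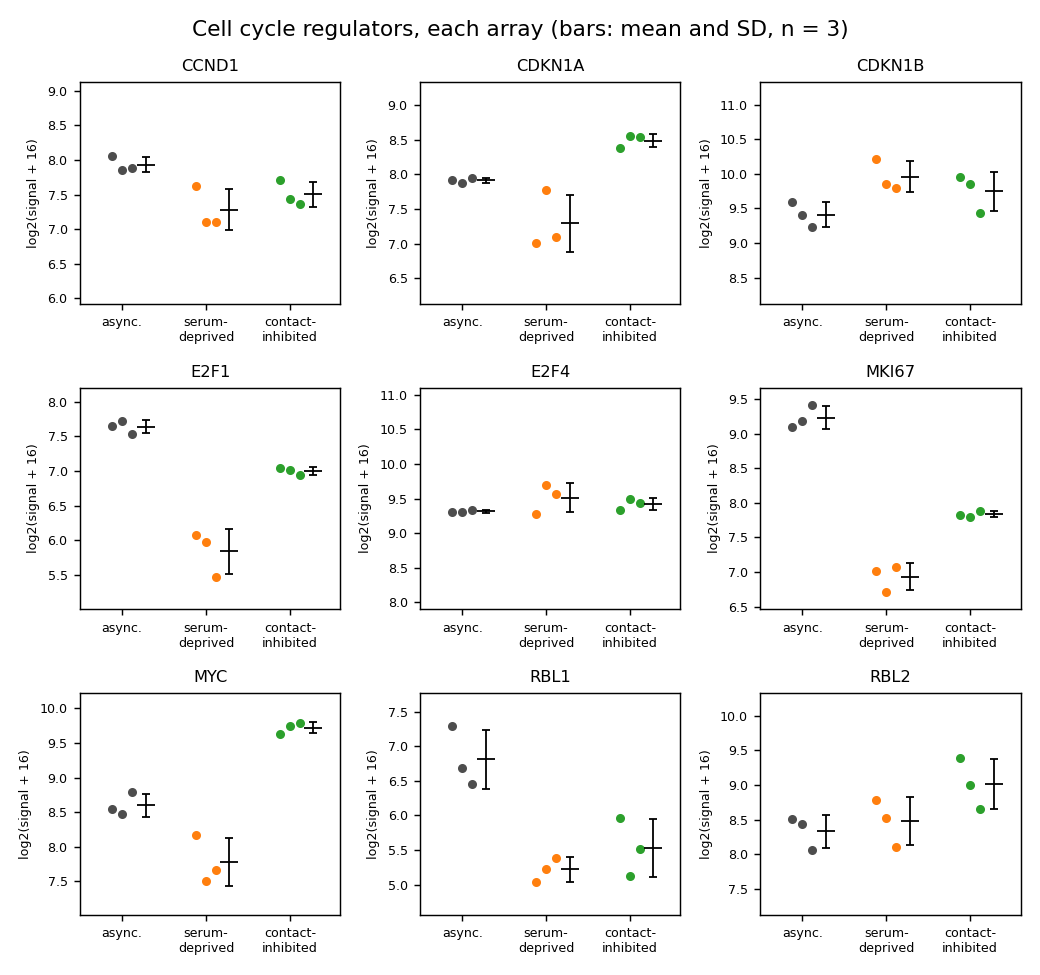
Normalized log2(intensity + 16) of 9 cell cycle regulators on each of 9 arrays, with points in the order of replicates 1 to 3 and bars giving the mean and SD of 3 arrays per group. MYC averaged 8.60 in asynchronous, 7.78 in serum-deprived and 9.72 in contact-inhibited cells.

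Adjusted over the list alone, the counts were 51 and 51 lower for the G2/M list in serum-deprived and contact-inhibited cells, 43 and 41 for the G1/S list and 15 and 15 for the DNA repair list. Adjusted over the list alone, extracellular matrix genes were higher in 23 and 25 cases, lysosome genes in 31 and 26, interferon response genes in 25 and 11 and proteasome genes lower in 14 and 24. Cholesterol biosynthesis, glycolysis, cytosolic ribosomal protein, actin cytoskeleton, p53, YAP-TEAD, cell adhesion, Notch and Wnt, hypoxia, astrocyte, neuronal and immune lists were called in none of the 3 contrasts. Of these, glycolysis was at a median of −0.27 in serum-deprived cells (adjusted p = 0.0545), where it was called without contact-inhibited replicate 1 (0.0489), serum-deprived replicate 2 (0.0487) or asynchronous replicate 1 (0.0385), and with no filter (0.0236). YAP-TEAD targets were at 0.36 (adjusted p = 0.0545), and called without serum-deprived replicate 1 (0.043), contact-inhibited replicate 1 (0.0489) or asynchronous replicate 1 (0.0447), and with median centring (0.049), no filter (0.0264) or the mean of probe sets (0.0241). Astrocyte and glial markers in serum-deprived cells (median 0.21, adjusted p = 0.0708) were called with median centring (0.049) or the mean of probe sets (0.0181). The list of CDK inhibitors and growth arrest genes was at a median of 0.55 in serum-deprived cells (adjusted p = 0.114), and called without asynchronous replicate 1 (0.049). In serum-deprived cells the median and the mean or test of the TGF-beta (median 0.15, mean −0.28), NF-kB (median −0.04, mean 0.07) and unfolded protein (median 0.11, mean −0.13) lists differed in sign. The same held in contact-inhibited cells for fatty acid synthesis (median −0.10, mean 0.04), glycolysis, actin cytoskeleton, cell adhesion and astrocyte lists. Between the arrests it held for mitochondrial ribosome, cytosolic ribosomal protein, FOXO, chaperone, splicing, growth factor and neuronal lists, whose medians lay between −0.01 and 0.08. By fry, which compares a list with no other genes, 34 lists moved in serum-deprived and 34 in contact-inhibited cells against asynchronous ones, and 27 between the arrests.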

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

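The test on immune markers and the test on evenly mixed splits were chosen only after the results they bear on were seen, and the bounds for reading the tests on other probe sets and on immune markers were tightened after their values were seen.

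The arrests moved 187 genes in opposite directions against asynchronous cells, fewer than the 874 that independent lists would give. Each was also called in the direct contrast between the arrests. That adds no support, since the direct difference of such a gene is made up of both of its changes. Among those named by the fixed rule, the differences of serum-deprived minus contact-inhibited cells on the log2 scale were 3.70 for RGS2, −2.89 for RARRES1, −2.76 for MMP1, −1.94 for MYC, −3.55 for MMP13, −2.07 for ASNS, −2.13 for CHAC1, −1.20 for CDKN1A, 2.51 for PPP1R3C and 3.69 for HPGD. Most of the difference of HPGD and PPP1R3C was their rise in serum-deprived cells, 3.31 and 2.09. In contact-inhibited cells they fell by little, −0.38 (adjusted p = 0.0329) and −0.42 (adjusted p = 0.0243). Gene lists that differed in the direct contrast were G1/S and DNA replication (median −0.97), G2/M and mitosis (−1.77), DNA repair (−0.74), CDK inhibitors and growth arrest (−0.26), fatty acid synthesis (−0.24), nucleotide synthesis (−0.43), TGF-beta targets (−0.39), the unfolded protein and amino acid response (−0.24) and the proteasome (0.29). All but the first 3 of these lists lost their call with an estimated correlation (adjusted p = 0.0982 to 0.159). Probe sets that name several genes or were unnamed here stood outside the gene tests, and of 1450 above the filter 546, 584 and 404 were called for serum-deprived against asynchronous, contact-inhibited against asynchronous and serum-deprived against contact-inhibited cells.

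The deeper fall of mitotic genes in serum-deprived cells could come from growing cells that remained in the contact-inhibited cultures. The share of growing cells that each gene implies had a median of 29.8% over 43 G1/S genes and 40% over 51 G2/M genes. The difference was −10.2 percentage points (95% bootstrap interval over genes −16.3 to −2.53). These genes were read on the same arrays and are not independent replicates, so the interval holds no spread between arrays. It therefore cannot decide whether a single remainder of growing cells was the whole cause. The 320 other genes at least 2-fold lower in serum-deprived cells, which were outside that test, implied a median share of 29.5% (quartiles 15.4 to 47.6). These quartiles hold the medians of both lists. The genes were also picked by the same fall that the share is divided by, so their value does not help to decide. The scale of the arrays could also part the groups, but the median difference of the G2/M list was −1.62 or lower under each of 4 alternatives, 3 scalings and the 6 arrays of the larger batch alone, down to −1.88. A remainder of growing cells, alone or alongside a difference in gene control between the arrests, stays open, and the latter was not tested.

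The large falls of SFPQ and of other genes in contact-inhibited cells may be those of 1 form of a transcript read by some of the probe sets. The 5 other probe sets of 3 of the 6 genes with the largest falls had a median change of −0.48, with a bootstrap interval from −2.76 to 0.52. By the bound first set, above −0.5, this would have counted for the explanation, but the interval reaches far to both sides. For these genes as a set, the gene and a form of its transcript cannot be told apart with so few probe sets. The 2 probe sets of CDC6 both lay low, at −2.15 and −2.76, whereas those of SFPQ ran from −2.65 to 0.52, so only some of them read the fall of SFPQ. No biological explanation was tested.

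S100A8, S100A9, CHI3L1 and HLA-DRB1 were 3.16, 2.26, 3.66 and 2.19 higher on the log2 scale in contact-inhibited than in asynchronous cells, and by smaller amounts, 1.77, 0.48, 1.71 and 0.60, in serum-deprived cells. Blood or immune cells in the contact-inhibited cultures could be a source. The 15 immune markers on the array, with HLA-DRA and CD74 left out as genes other cells can turn on, had a median change of 0.05 (bootstrap interval −0.16 to 0.17), and 0 of them were higher by 1 or more. The labels name T98G cells, an established line, as the only source. Immune cells would thus have to be a contamination, of which these 15 markers gave no sign. Only 3 lay above the filter (CD53 −0.006, ITGAM 0.237 and LCP1 0.157). How far the others would move depends on a share of immune cells that the arrays do not give. The markers alone therefore cannot exclude a small share of such cells. A change within the T98G cells was not tested.

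Each of the 3 gene counts was reached by 1 of 10 splits of the 6 arrays compared, the real one, which are too few splits for a share under 0.05. The real counts were 3585, 3708 and 2858 and the highest other count was 0 in each case. Over 100 drawn splits of the 9 arrays, 1 reached the 2264 genes shared by both arrests (highest other 1547). Likewise, 1 reached the 4743 genes that differed among the groups (highest other 1777). In both cases this was the real split, so no other drawn grouping of these arrays reached either count. Splits that mix the groups carry the group differences into the spread between arrays. The splits therefore cannot exclude a chance difference between the cultures. For the 50 lists called over the 3 contrasts, 14 of the 100 splits called as many and the highest other called 57. By the bound set in advance, chance was not excluded for the list count. Arrays of one group left together in a split may be the source of such counts. Of 17 drawn splits with 1 array of each group in every part, 0 reached 50 lists and the highest called 1. The other 82 called a median of 41.5 and at most 57. An even split balances the groups in every contrast, so few calls followed from its design. The uneven splits still hold differences between the groups. Neither kind of split therefore decides whether the list count could arise by chance.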

How the results depend on the processing

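Scaling to a common trimmed mean, the scaling batch as a block and the 6 arrays of the larger batch alone were chosen only after the data were seen. Counts are given in the order serum-deprived against asynchronous, contact-inhibited against asynchronous, serum-deprived against contact-inhibited, and shared by both arrests. The counts of 3585, 3708, 2858 and 2264 genes stayed within 1.5 times under all but 3 alternatives. They were 1313, 940, 597 and 546 with no normalization, of which 1295, 934, 591 and 538 were also called in the main setting. Without x and s probe sets, where 5215 genes were tested in place of 7607, they were 2159, 2266, 1748 and 1318, with a correlation of 0.627 between the arrests, and at least 2-fold changes numbered 721, 611, 431 and 299. Why fewer genes passed without normalization was not tested. With the replicate number as a block the counts were 4081, 4225, 3474 and 2635 and the correlation 0.659. The block ended the direct calls of the CDK inhibitor and growth arrest (adjusted p = 0.0525), fatty acid (0.058) and TGF-beta (0.0535) lists, and made calls of CDKN1B in contact-inhibited cells (0.00227) and between the arrests (0.0399). Deviations from the group means correlated at 0.0655 to 0.386 in the 9 pairs of arrays with one number and at −0.387 to 0.184 in the others, and 7 of 9 arrays matched best with their own number in both other groups. Since serum-deprived and asynchronous replicate 2, at 0.0655, fell below the bound of 0.1 set for every pair, the numbers were not taken to pair the arrays, though all 3 serum-deprived and contact-inhibited pairs (0.173 to 0.323) and contact-inhibited and asynchronous pairs (0.131 to 0.386) lay above it, and the better match is a hint from the data alone. Leaving out 1 array gave 3105 to 3641, 3153 to 3759, 2351 to 2895 and 1912 to 2211 genes and a correlation of 0.641 to 0.671. Of named genes, 3 values turned their direction when an array was left out, 12 lost their call, 4 gained one and 1416 did neither, and under other alternatives these numbers were 2, 30, 7 and 2457. NRG1 in serum-deprived against asynchronous cells went from 1.24 to −0.56, −0.21 and −0.38 without serum-deprived replicate 1, 2 or 3, with a range of −0.56 to 1.34 over all arrays left out, because another of its probe sets was then the brightest. E2F4 in contact-inhibited cells was −0.35 and called (adjusted p = 0.015) as the mean of its probe sets, which gave 0.10 and −0.81. SFPQ in contact-inhibited cells was 0.12 without x and s probe sets, which left 1 of its 4 probe sets. Of list results, 0 turned direction in the test; 12 lost and 10 gained a call when an array was left out, and 35 and 55 under other alternatives, including the estimated correlation and fry. Without normalization the medians of the matrix protease and growth factor lists in serum-deprived cells were −0.05. Signal over background limits dim genes, whose changes are understated.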

Other observations

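No test is reported in this part beyond those of the report, and the genes named here were chosen after their values were seen.

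The serine synthesis enzymes PHGDH and PSAT1 fell in both arrests, with changes of −1.79 and −1.73 in serum-deprived and −0.77 and −0.51 in contact-inhibited cells, and the amino acid transporter SLC7A5 changed by −2.30 and −1.18. ASNS and the cystathionine lyase CTH moved in opposite directions, by −1.44 and −0.70 in serum-deprived and by 0.63 and 1.17 in contact-inhibited cells. The collagenases MMP1 and MMP13 also did so, at −1.91 and −2.79 in serum-deprived and 0.85 and 0.76 in contact-inhibited cells, as did the hexokinase HK2 (−0.61 and 0.78) and, in the reverse sense, PIK3R1 (0.71 and −0.70). In all, 106 genes were higher in serum-deprived and lower in contact-inhibited cells and 81 the reverse.

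Of the TGF-beta targets, a list called in neither arrest against asynchronous cells, 6 were higher and 6 lower of 16 in serum-deprived cells and 7 and 6 in contact-inhibited cells, with ID1, ID3, SMAD6 and BAMBI lower in both. CCN2, a matricellular protein, rose by 2.23 in serum-deprived and 1.26 in contact-inhibited cells. The glial lipoprotein genes CLU (1.71 and 1.96) and APOE (0.88 and 0.97) and the neuronal enolase ENO2 (1.38 and 1.11) were higher in both arrests. Their lists were called in neither arrest: of 10 astrocyte and glial markers 5 were higher and 0 lower in serum-deprived and 3 and 2 in contact-inhibited cells (median −0.13), and of 6 neuronal markers 3 were higher and 1 lower, and 2 and 1. In contrast, IGFBP3 was lower, at −0.67 and −1.92. Of genes called in only one arrest, 734 of 1134 for serum deprivation and 776 of 1257 for contact inhibition also differed between the arrests in the direct contrast.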
